A study of Homo sapiens with 6 samples.

How the data were processed

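Total RNA from control RWPE1 prostate epithelial cells and from RWPE1 cells overexpressing ODC1 was labelled with biotin as cRNA and hybridised to Illumina arrays, per the labels' protocols, with 3 arrays in each of the 2 groups. The deposited values were linear probe intensities of 47322 probes per array. They reached from −13.3 to 13553.3, about 26.4% of the values on each array were negative, and the sorted values of the arrays differed by at most 0.2. From these values, the authors' intensities were background-subtracted and quantile normalized between arrays, and they were not log transformed. The software and the background method behind the deposited intensities are not given in the sources used here. No detection p-values were used here.

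Groups and replicate numbers were taken from the sample labels. Each array was raised by 1 minus its own minimum, which added 14.3 to every array, then log2 was taken and the arrays were quantile normalized with limma, which moved values by at most 0.06. Differences are therefore on the scale of log2(intensity + 14.3), which understates the change of dim genes. For a gene with a group at or under the array median of 4.4 the size of the log2 difference depends on the added 14.3, so levels alone are given for KRT19, TWIST1 and GREM1. Values named as a level are deposited intensities, as mean ± SD over 3 arrays. Probe names came from the platform's annotation, in which 30113 probes had 1 gene symbol, 8 had several and 17201 had none here. Entrez identifiers of 30074 probes matched the RefSeq gene table of assembly GRCh38.p14, and 0 symbols changed. For 2 list genes the current symbol replaced an older one. A gene with several probes (6691 genes) was represented by the probe with the highest mean over the 6 arrays, which gave 20046 genes, and no filter on dim probes was applied. The array's own genome build is not given in the sources used here, so no coordinates are printed, and gene span was taken from the RefSeq table for 20020 genes.

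The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend), two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. For 25 gene lists of 843 distinct genes, of which 787 were measured, camera was run with its correlation preset to 0.01 and again with an estimated correlation. Adjustment was over the 25 lists, ODC1 was left out of the polyamine list in the test, and fry was an alternative. Camera asks whether the test statistics of a list's genes are on average higher or lower than those of other genes. Fry asks whether a list's genes move one way on balance. An array's deviation for a list is the median over its genes of the log2 level minus the gene's mean over 6 arrays. The lists, the tests and the rule for naming genes were fixed before the data were examined. The rule named ODC1, a fixed set of polyamine, androgen and epithelial genes, up to 10 genes per direction with the largest change among those past the threshold, completely separated and above the 75th percentile of the brighter group, and from each list up to 4 members past the threshold or, with none, its 2 brightest members.

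The procedure was tested on simulated data with 3 arrays against 3, 20046 genes and 200 changed genes in each of 10 simulations. It recovered 13.1% of genes changed 1.5-fold, 83.4% of those changed 2-fold and 99.8% of those changed 4-fold, with 7.24% false among the calls. A shifted list was recovered in 20 of 20 simulations, and 1 of 480 unchanged lists was called. The simulated genes were drawn independently of each other, so these rates do not cover lists whose genes move together. In the measured arrays the estimated correlation was 0.25 for the oxidative phosphorylation list and 0.84 for the interferon list. The alternatives were the replicate number as a block, each array left out in turn, an intensity trend with and without robust fitting, centring on the median or the 75th percentile in place of quantile normalization, an offset of 50, normexp background correction with an offset of 50, leaving out probes under the median level, the mean of all probes of a gene, and a stricter threshold of 0.01. Array quality weights and an adjustment of each array for a lowess trend on gene span were chosen after seeing the data. TP63 was not analysed here, and some other items of the naming rule are not reported here.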

Results

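Gene expression was measured on Illumina bead arrays in RWPE1 cells, a line of normal human prostate epithelial cells immortalised with papillomavirus DNA, and in RWPE1 cells carrying a plasmid that expresses ODC1. ODC1 encodes ornithine decarboxylase, which makes putrescine from ornithine in the first step of polyamine synthesis. The series asks which pathways differ once ODC1 is overexpressed. The 6 arrays form 2 groups, 3 control arrays and 3 ODC1 overexpression arrays. Each array holds 47322 probes, and the probes with a single gene name give 20046 genes. The number of arrays limits the precision. The labels do not say whether the 3 arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

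ODC1 itself was higher on average in the ODC1 overexpression arrays, at an intensity of 1456 ± 261 against 1118 ± 243 in control (mean ± SD, n = 3 each), but the groups overlapped. The control arrays gave 852.3, 1170.9 and 1329.9, and the ODC1 overexpression arrays gave 1546.6, 1660.5 and 1161.8. The log2 difference of the single ODC1 probe was 0.39 (SE 0.21, 95% interval −0.09 to 0.86), a fold change of 1.31, and it did not pass the test (limma adjusted p = 0.585). ODC1 overexpression replicate 3 was lower than control replicates 2 and 3. None of the other polyamine genes passed either. AMD1, which makes the decarboxylated S-adenosylmethionine used for spermidine and spermine, had a log2 difference of 0.43 (SE 0.20, adjusted p = 0.541). SAT1, the acetyltransferase that starts polyamine breakdown, had 0.42 (SE 0.26, adjusted p = 0.622). The spermidine synthase gene SRM had −0.15 (SE 0.18), the spermine synthase gene SMS 0.06 (SE 0.18), the antizyme gene OAZ1 −0.02 (SE 0.16), and the antizyme inhibitor gene AZIN1 −0.21 (SE 0.19). SLC3A2, a bright member of the list, had 0.19 (SE 0.23). Of the 25 measured members of the polyamine list, ODC1 included, 14 were higher, 11 were lower and 25 did not pass, over all genes or adjusted over the list alone. Without ODC1 the list's median was 0.03, its mean was 0.01 and the camera test pointed down (adjusted p = 0.934). Camera compares a list with the other genes, and the median log2 difference of all genes was 0.025. A list slightly above 0 can therefore point down without a conflict.

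In ODC1 overexpression 6 named genes rose, each more than 2-fold on the scale of log2(intensity + 14.3), and all 3 ODC1 overexpression arrays lay above all 3 control arrays for each. PTGS2, the inducible cyclooxygenase of prostaglandin synthesis, rose by 2.17 on the log2 scale (SE 0.23, adjusted p = 0.0212), from an intensity of 19.6 ± 10.4 to 133 ± 9.67. MMP13, a matrix metalloproteinase that cleaves collagen, rose by 1.93 (SE 0.26, adjusted p = 0.0444), from 96.0 ± 30.3 to 411 ± 138. CA2, a cytosolic carbonic anhydrase, rose by 1.26 (SE 0.16, adjusted p = 0.0251), from 1147 ± 13.4 to 2766 ± 137, and its second probe gave a log2 difference of 1.31. RASD1, a dexamethasone-inducible Ras-related GTPase, rose by 1.45 (SE 0.17, adjusted p = 0.0212). PALM, which encodes the membrane-associated protein paralemmin, rose by 1.51 (SE 0.17, adjusted p = 0.0212) on its brightest probe, whereas its other 2 probes, both dim, gave 0.16 and 0.20. KRT19, a keratin of simple epithelia, rose (adjusted p = 0.0212) from 1.23 ± 3.23, under the array median on every control array, to a dim 35.0 ± 5.94.

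**Figure D1:**
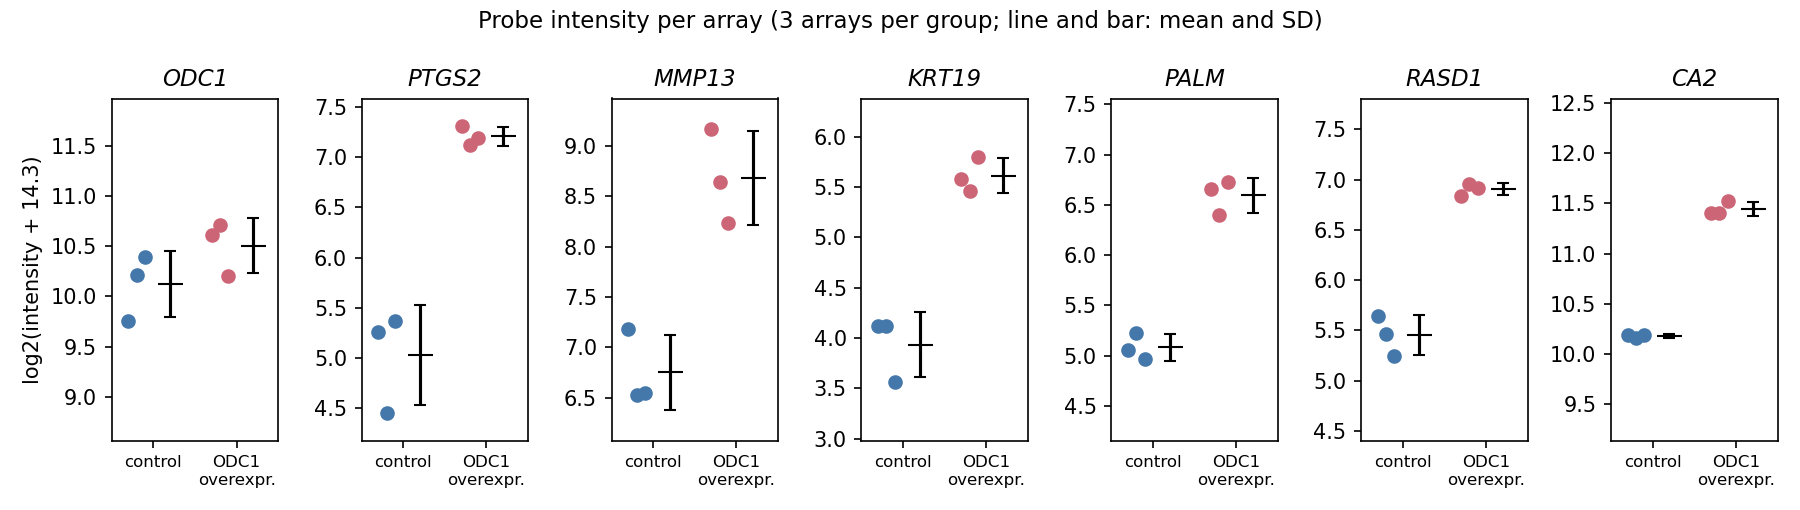
Level of ODC1 and of the 6 genes past the threshold on each array, as log2 of intensity plus 14.3, for control (blue) and ODC1 overexpression (red). Points are single arrays, the horizontal line and bar are the mean and SD of 3 arrays, and every panel spans the same log2 range. The ODC1 groups overlap, while for each of the other 6 genes all ODC1 overexpression arrays lie above all control arrays.

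No gene passed the threshold in the other direction. Limma counted 6 higher and 0 lower at an adjusted p under 0.05, and 937 higher and 1000 lower at an unadjusted p under 0.05. At an adjusted p under 0.10 it counted 11 higher and 1 lower. The lower gene, GNG11, a G protein gamma subunit, and the 5 further higher genes, ACKR3, CPE, CTHRC1, KIT and EPDR1, were named after their values were seen. GNG11 had a log2 difference of −1.39 (SE 0.21, adjusted p = 0.0731). The arrays of the 2 groups were completely separated for 15.06% of genes. The average over the 10 splits of the 6 arrays into 3 and 3 is 10%. Genes move together, so a single split may lie above this without a group effect. The share in the other splits was not tested, so the excess cannot be read as a group effect. Leaving out any 1 of the 6 arrays, with 1 array fewer in the fit, left 0 calls (573 to 1179 genes higher and 653 to 1198 lower at an unadjusted p under 0.05), with adjusted p values for PTGS2 from 0.0502 to 0.129. The log2 differences stayed about as large, from 1.89 to 2.34 for PTGS2, 1.69 to 2.15 for MMP13, 1.44 to 1.605 for PALM, 1.35 to 1.55 for RASD1 and 1.22 to 1.28 for CA2. With an intensity trend in the variance model the counts were 33 higher and 11 lower, and without dim probes they were 16 higher and 2 lower, the 6 genes among them each time.

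Among the 25 fixed gene lists, 6 were shifted upwards and 3 downwards by camera with its preset correlation, while 0 were called with an estimated correlation. The estimated correlation between a list's genes reached from −0.039 for the neuroendocrine markers to 0.84 for the interferon list. For the neuroendocrine markers and the androgen-regulated genes (−0.0056) it lay below the preset 0.01. Genes moving together therefore do not account for the loss of these calls. Without control replicate 1 the number called was 5. The 6 arrays were also split into 3 and 3 in other ways, a check chosen after the results were seen. Each of these other splits called lists too, from 3 to 9 of them, so the number called does not set the labelled groups apart. The lists held 787 measured genes, of which PTGS2 and KRT19 rose over all genes tested and the rest did not pass.

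The largest downward shift among the lists was in oxidative phosphorylation, the genes of the mitochondrial respiratory chain and ATP synthase. Of its 42 measured members 32 were lower and 10 higher, with a median log2 difference of −0.34 (camera adjusted p = 9.88e-09, adjusted p = 0.572 with an estimated correlation). No member passed over all genes, and 12 fell when adjusted over the list alone. Among these, named after their values were seen, were the complex I subunits NDUFC1 (−0.89, SE 0.21), NDUFS8 (−0.85, SE 0.23) and NDUFA1 (−0.79, SE 0.20) and the cytochrome oxidase subunit COX5B (−0.80, SE 0.24). NDUFA1 had an intensity of 1319 ± 278 in control and 750.1 ± 113 in ODC1 overexpression. Of the 2 brightest members, COX7C had a log2 difference of −0.40 (SE 0.19) and the ATP synthase subunit ATP5F1B 0.16 (SE 0.16), and neither passed. Ribosomal protein genes moved with the list, with a median of −0.31 over 77 genes, 65 of them lower. Both the list and the ribosomal protein genes also varied within the groups. The list's median deviation was 0.23, 0.0045 and 0.39 in control replicates 1, 2 and 3, and −0.26, −0.29 and −0.0011 in ODC1 overexpression replicates 1, 2 and 3. Genes with a short span in the annotation were lower in general, with a median log2 difference of −0.12 in the shortest of 10 equal groups of brighter genes and 0.09 in the group ranked 8.

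**Figure D2:**
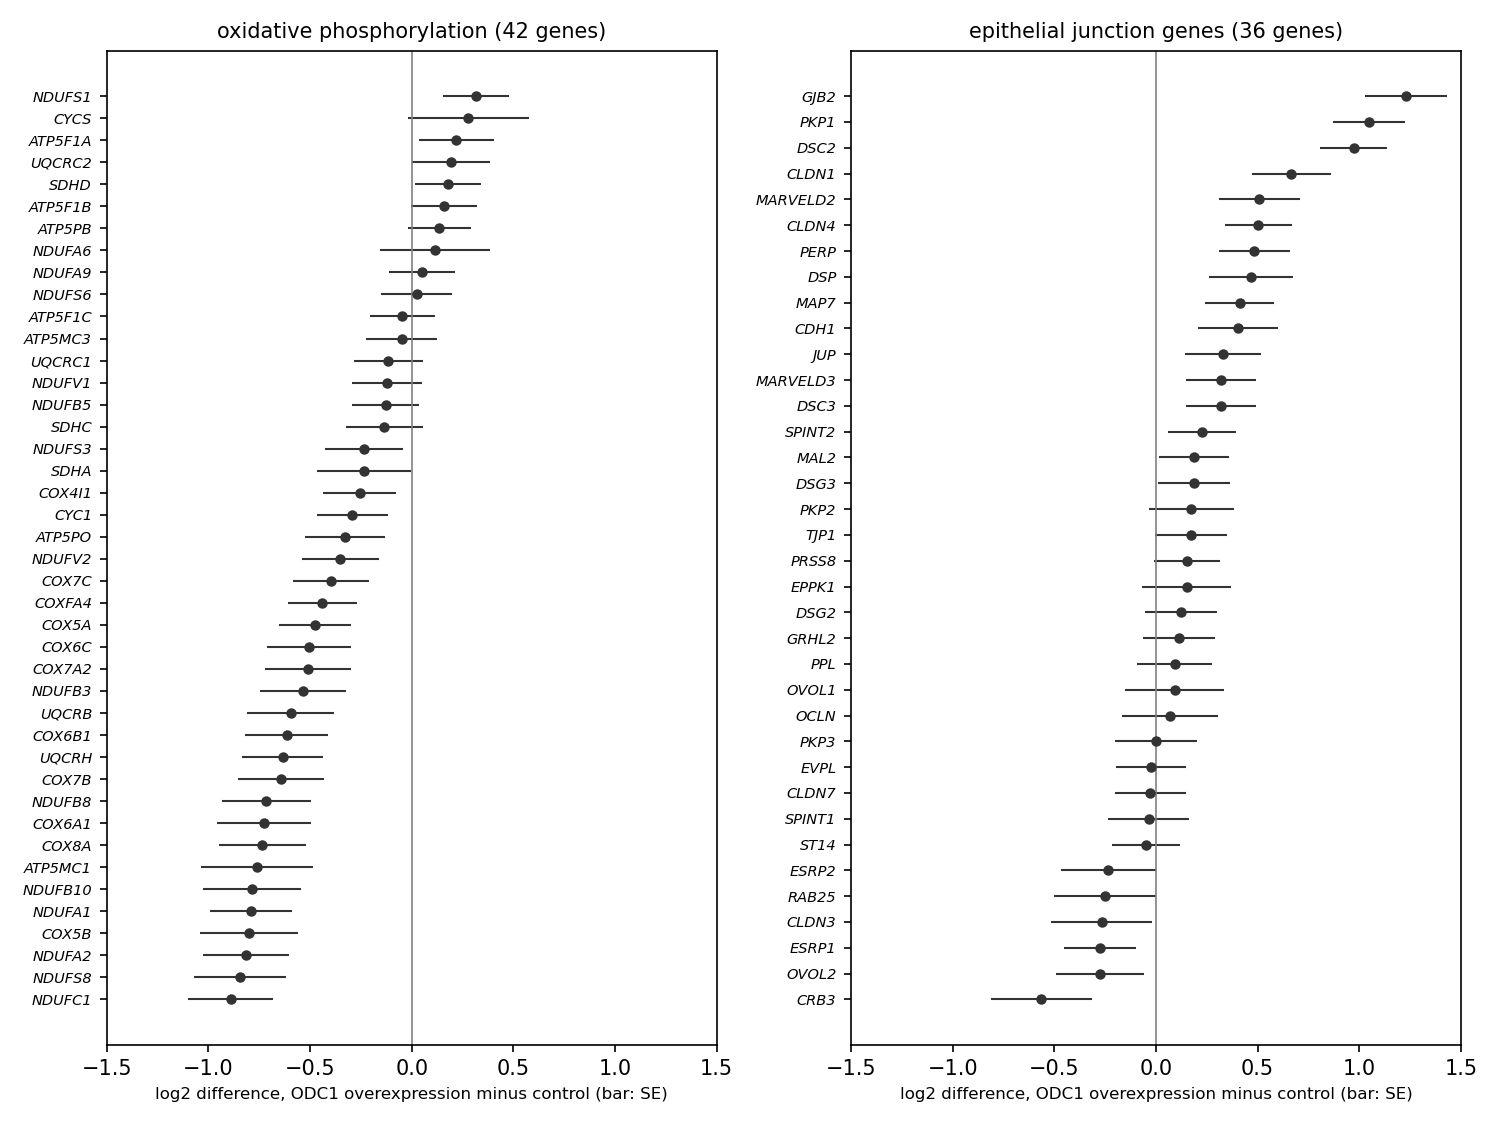
Log2 difference (ODC1 overexpression minus control) of each measured gene of the oxidative phosphorylation list (42 genes, left) and of the epithelial junction list (36 genes, right). Points are limma estimates from 3 arrays per group and bars are 1 SE. Of the oxidative phosphorylation genes 32 lie below 0, and of the junction genes 25 lie above 0, with GJB2, PKP1 and DSC2 at the top.

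Epithelial junction genes were shifted upwards. Of 36 measured members 25 were higher and 11 lower, with a median of 0.16 (camera adjusted p = 0.00118, adjusted p = 0.572 with an estimated correlation). The list's median deviation was −0.05, −0.03 and −0.26 in control replicates 1, 2 and 3, and without control replicate 3 the median was 0.060 (adjusted p = 0.0463). None passed over all genes, and 3 rose when adjusted over the list alone, which are named for that reason after their values were seen. The gap junction gene GJB2 rose by 1.23 (SE 0.20), from an intensity of 1158 ± 118 to 2775 ± 620. The desmosome genes PKP1 and DSC2 rose by 1.05 (SE 0.18) and 0.97 (SE 0.16) on their brightest probes. The other probe of PKP1, which was dim, gave 0.03, and the other probe of DSC2 gave 0.72. E-cadherin, CDH1, had a log2 difference of 0.40 (SE 0.20, adjusted p = 0.546), and the bright members SPINT2 and PERP had 0.23 (SE 0.17) and 0.48 (SE 0.17). The mesenchymal and EMT list was not called (median 0.04, camera adjusted p = 0.724), with 27 members higher and 17 lower of 44. VIM, the mesenchymal intermediate filament gene, had −1.02 (SE 0.42, adjusted p = 0.482) with control arrays at 3069 ± 1436 and ODC1 overexpression arrays at 1500 ± 815. TWIST1, an EMT transcription factor named after its values were seen, was the single member that passed when adjusted over the list alone. It fell from a dim 11.3 ± 1.5 to 0.733 ± 1.55, under the array median. The bright members THBS1 and TGFBI had 0.52 (SE 0.22) and 0.58 (SE 0.33).

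Androgen-regulated genes, a list chosen because the series title concerns androgen signaling, were shifted upwards by a small amount. Of 44 measured members 31 were higher and 13 lower, with a median of 0.15 (camera adjusted p = 0.0106, adjusted p = 0.572 with an estimated correlation). KRT19 rose over all genes, and KRT19 and TMPRSS2 rose when adjusted over the list alone. TMPRSS2, an androgen-induced serine protease, had a log2 difference of 0.90 (SE 0.22, adjusted p = 0.302 over all genes) at low intensities of 9.0 ± 5.07 and 29.0 ± 8.90. KLK3, which encodes prostate-specific antigen, lay near background in both groups, at 0.333 ± 2.12 and 2.77 ± 1.42. FKBP5, a glucocorticoid and androgen target, had a log2 difference of 0.13 (SE 0.17). Part of the list was dim, with mean log2 levels under 4.141, the level that set brighter genes apart. Of these dim members KLK2, KLK3, STEAP4, SPDEF and ACP3 were higher, and ORM1, PPFIA2, TRPM8, AZGP1 and MSMB were lower. No detection p-values were used, so whether these members are expressed was not tested. The list's median deviation was above 0 in all 3 ODC1 overexpression arrays and below 0 in all 3 control arrays. Without control replicate 3 the median was 0.097 (adjusted p = 0.0332). After adjustment of each array for the trend with gene span, an alternative chosen after seeing the data, the median was 0.08 and the list was not called (adjusted p = 0.0848). The list of nuclear receptor cofactors and androgen synthesis genes was not called (median 0.13, camera adjusted p = 0.277), with 16 members higher and 12 lower of 28, although fry called it together with the androgen-regulated list (adjusted p = 0.045 for each). Without ODC1 overexpression replicate 1 its median was 0.043 (adjusted p = 0.39). Its bright members HSP90AA1 and NCOA4 had 0.42 (SE 0.21) and 0.30 (SE 0.16).

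Heat shock proteins and the glycolysis and hypoxia genes were shifted upwards as well. Of 20 heat shock genes 19 were higher, with a median of 0.35 (camera adjusted p = 0.000653, adjusted p = 0.572 with an estimated correlation), and none passed on its own, over all genes or adjusted over the list alone. The small chaperone HSPB1 had 0.21 (SE 0.17). The heat shock call was lost without control replicate 1, where the median was 0.17 (adjusted p = 0.0579). Of 37 glycolysis and hypoxia genes 28 were higher and 9 lower, with a median of 0.25 (camera adjusted p = 0.000745, adjusted p = 0.572 with an estimated correlation), and none passed on its own by either adjustment. The median deviation of the glycolysis and hypoxia list was −0.27, −0.09 and −0.03 in control replicates 1, 2 and 3. It was 0.20, 0.19 and −0.04 in ODC1 overexpression replicates 1, 2 and 3, so replicate 3 lay at the level of control replicate 3. The glycolytic enzymes LDHA and ENO1 had 0.25 (SE 0.20) and 0.33 (SE 0.19).

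Type I interferon response genes had the largest upward median among the lists, 0.44, with 36 of 42 members higher (camera adjusted p = 0.00118, adjusted p = 0.928 with an estimated correlation). No member passed over all genes, and SAMD9, an antiviral factor named after its values were seen, rose by 1.06 (SE 0.21) when adjusted over the list alone. The bright members IFITM2 and IFITM3, which restrict virus entry, had −0.29 (SE 0.22) and −0.61 (SE 0.29). The list's level varied widely inside each group, with a median deviation of 1.04, −0.41 and −0.21 in ODC1 overexpression replicates 1, 2 and 3 and of 0.37, −0.30 and −0.54 in control replicates 1, 2 and 3. Without ODC1 overexpression replicate 1 the median was −0.14 (adjusted p = 0.278), and the call was also lost without control replicate 2 (0.29, adjusted p = 0.0983) and without control replicate 3 (0.18, adjusted p = 0.182). The median was 0.72 without control replicate 1 and 0.68 without ODC1 overexpression replicate 2.

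**Figure D3:**
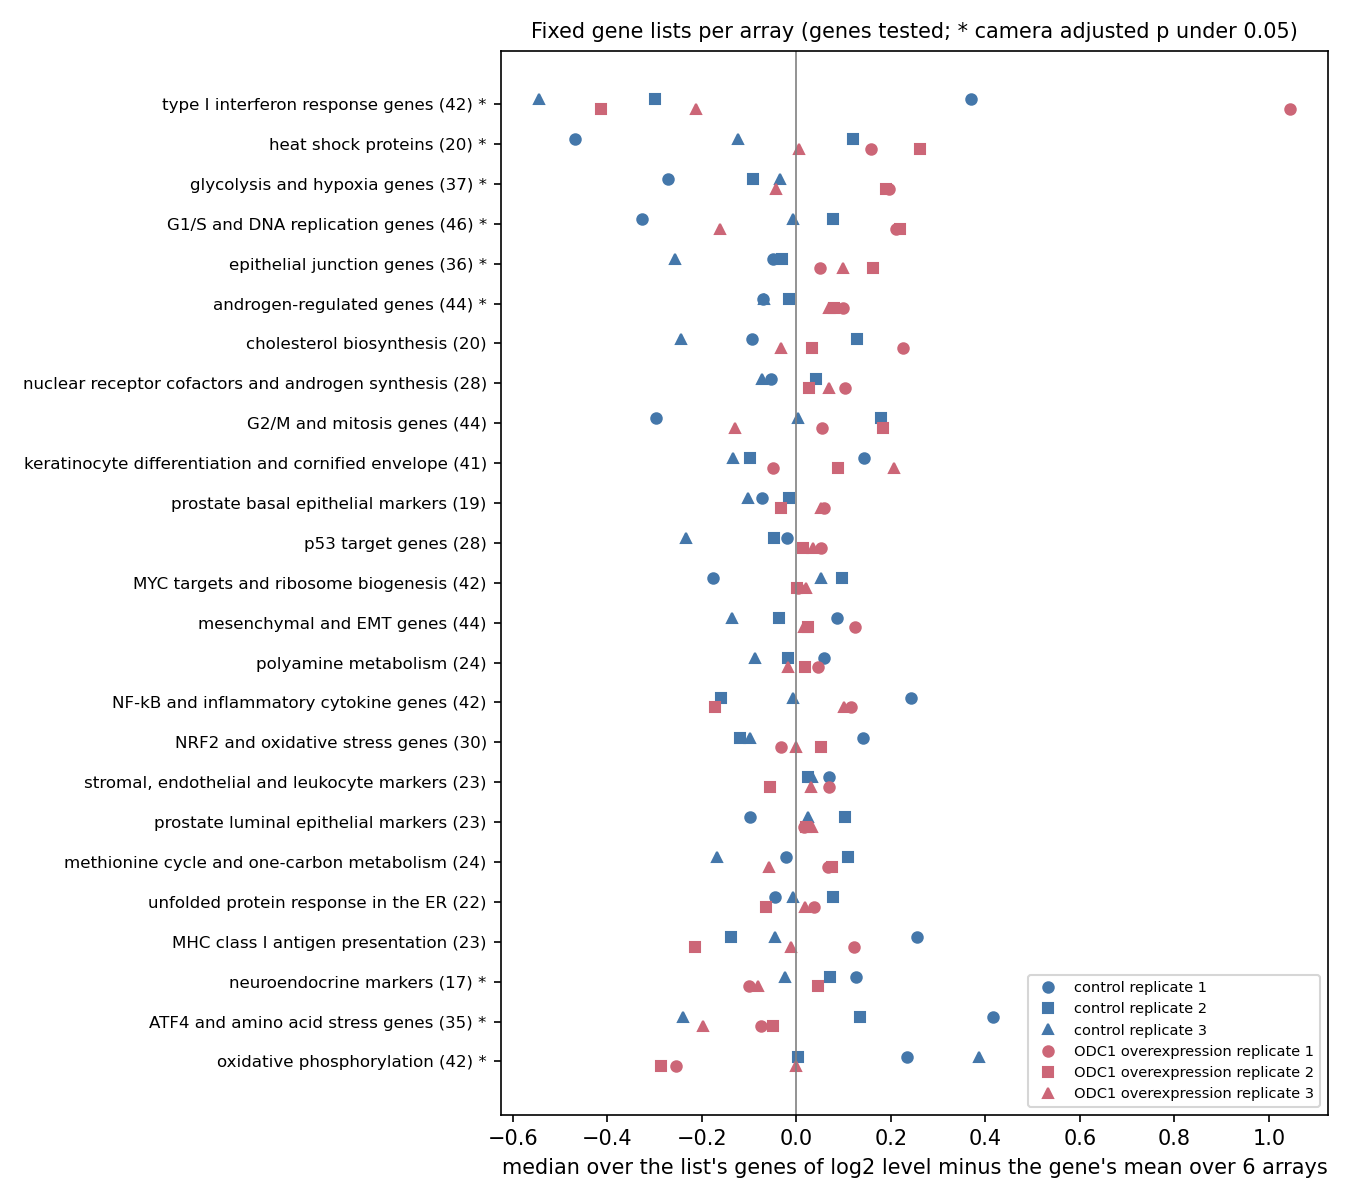
Median over each fixed list of the log2 level minus the gene's mean over the 6 arrays, for control (blue) and ODC1 overexpression (red), with circles, squares and triangles for replicates 1, 2 and 3. Lists are ordered by their median log2 difference, numbers in parentheses are genes tested, and an asterisk marks a camera adjusted p under 0.05. ODC1 overexpression replicate 1 stands at 1.04 for the interferon list, and the androgen-regulated list lies between −0.07 and 0.10 on every array.

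G1/S and DNA replication genes were shifted upwards, with 37 of 46 members higher and a median of 0.19 (camera adjusted p = 0.0106, adjusted p = 0.928 with an estimated correlation). None passed by either adjustment, and the bright members ORC6 and PCNA had 0.24 (SE 0.17) and 0.19 (SE 0.18). This call was lost without control replicate 1 (median 0.05, adjusted p = 0.784), without ODC1 overexpression replicate 1 (0.12, adjusted p = 0.121), without ODC1 overexpression replicate 2 (0.12, adjusted p = 0.275) and after adjustment for gene span (0.14, adjusted p = 0.0533), and the median was 0.31 without ODC1 overexpression replicate 3. The G2/M and mitosis list was not called (median 0.13, adjusted p = 0.616), with 29 members higher and 15 lower, and its bright members BUB3 and CDC20 had 0.18 (SE 0.18) and 0.14 (SE 0.23).

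ATF4 and amino acid stress genes were shifted downwards, with 24 of 35 members lower and a median of −0.17 (camera adjusted p = 0.00665, adjusted p = 0.823 with an estimated correlation). None passed by either adjustment. The transcription factor ATF4 had 0.24 (SE 0.17) on its brightest probe and −0.07 and −0.24 on the other 2, and the amino acid transporter SLC7A5 had 0.18 (SE 0.20). The call was lost without control replicate 1 (−0.10, adjusted p = 0.149) and without ODC1 overexpression replicate 3 (−0.16, adjusted p = 0.069), and the median was −0.33 without control replicate 3 and −0.28 without ODC1 overexpression replicate 2. The neuroendocrine markers were lower in 13 of 17 members, with a median of −0.14 (camera adjusted p = 0.0495, adjusted p = 0.572 with an estimated correlation). None passed by either adjustment, and the call was lost without any 1 of the 6 arrays (medians −0.17 to −0.08, adjusted p from 0.0638 to 0.121). The brightest members, ENO2 and SOX2, had 0.01 (SE 0.21) and −0.30 (SE 0.25). Mean intensities in control and ODC1 overexpression were 40.7 and 40.3 for ENO2 and 30.1 and 22.6 for SOX2. These lay under the 75th percentile of 45.3 on the arrays, and the other members were dimmer. The shift of this list therefore rests on dim genes, and whether these markers are expressed was not tested.

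Neither the basal nor the luminal list of prostate epithelial markers was called. The basal list had a median of 0.08 (camera adjusted p = 0.475), with 13 of 19 members higher, and the luminal list −0.02 (adjusted p = 0.854), with 11 of 23 higher. The basal keratins KRT5 and KRT14 had log2 differences of 0.31 (SE 0.17) and 0.19 (SE 0.17), and the luminal keratins KRT8 and KRT18 had −0.02 (SE 0.19) and 0.00 (SE 0.18). TP63 was not analysed here. DKK3, another bright basal member, had 0.01 (SE 0.17), and the luminal members CD24 and KRT7 had 0.63 (SE 0.17, adjusted p = 0.312) and −0.10 (SE 0.18). Markers of stromal, endothelial and leukocyte cells were not called (median −0.02, mean −0.00028, adjusted p = 0.844), with 11 of 23 higher, and CD68 and CSF1R had −0.03 (SE 0.22) and 0.25 (SE 0.21).

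The remaining lists were not called by camera. NF-kB and inflammatory cytokine genes had 23 of 42 members higher (adjusted p = 0.844), and their median of 0.0090 and mean of −0.01 differed in sign. PTGS2 and the chemokine gene CXCL6, the latter named after its values were seen, rose when adjusted over that list alone, CXCL6 by 0.86 (SE 0.21). Cholesterol biosynthesis had a median of 0.13 (adjusted p = 0.222), with 14 of 20 members higher. SC5D, a sterol desaturase named after its values were seen, rose by 0.87 (SE 0.18) when adjusted over the list alone, while MSMO1 and SQLE had 0.22 (SE 0.20) and 0.26 (SE 0.23). Keratinocyte differentiation had a median of 0.09 (adjusted p = 0.277), with 25 of 41 higher. KRT16 and KLK5 had 0.33 (SE 0.17) and −0.42 (SE 0.19), and after adjustment for gene span the list was called upwards (0.22, adjusted p = 0.0258). MHC class I antigen presentation had −0.06 (adjusted p = 0.287), with 17 of 23 lower, and B2M and ERAP2 had 0.25 (SE 0.18) and 0.15 (SE 0.20). The p53 targets had 0.08 (adjusted p = 0.517), with 18 of 28 higher, and CDKN1A and ZMAT3 had 0.30 (SE 0.16) and 0.08 (SE 0.22). With each array left out in turn, the median of the p53 list was 0.014 to 0.17. MYC targets and ribosome biogenesis had a median of 0.04 and a mean of −0.01 (adjusted p = 0.844), with 24 of 42 higher, and HSPD1 and NCL had 0.23 (SE 0.18) and 0.11 (SE 0.17). The unfolded protein response had −0.03 (adjusted p = 0.762), with 13 of 22 lower, and HSP90B1 and SEC61B had 0.34 (SE 0.17) and −0.39 (SE 0.20). NRF2 and oxidative stress genes had 0.0036 (adjusted p = 0.844), with 15 of 30 higher, and TXN and FTL had −0.16 (SE 0.18) and −0.17 (SE 0.20). The methionine cycle and one-carbon list had −0.03 (adjusted p = 0.891), with 15 of 24 lower, and AHCY and PHGDH had 0.17 (SE 0.19) and −0.07 (SE 0.20).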

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

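The test over all probes, named or not, was chosen after the gene results were seen. One probe without a gene name here, outside the gene-level comparison, was higher in ODC1 overexpression, with a log2 difference of 2.04 (SE 0.20, limma adjusted p = 0.0136 over all 47322 probes) and intensities of 32.2 ± 5.78 in control and 178 ± 34.6 in ODC1 overexpression (n = 3 each).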

How the results depend on the processing

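Array quality weights and the adjustment for gene span were alternatives chosen after seeing the data, and the others were fixed before. ODC1 stayed higher and short of the threshold under every alternative, with a log2 difference of 0.20 to 0.54 when each array was left out in turn. The count of 6 genes higher and 0 lower was the same with centring on the median or the 75th percentile. It was 33 higher and 11 lower with an intensity trend (27 and 5 of them at least 2-fold) and 35 higher and 16 lower with a trend and robust fitting (27 and 9 at least 2-fold). It was 16 higher and 2 lower without dim probes (15 and 2 at least 2-fold), where fewer genes were tested, and the cause of the higher counts with a trend was not tested. An offset of 50 gave 9 higher, 3 of them at least 2-fold, and normexp with an offset of 50 gave 7 higher, 2 of them at least 2-fold, and each kept 4 of the 6 genes; an added offset shrinks the fold of dim genes by construction. With the mean of all probes 4 of the 6 were called, with array weights 7 including the 6, and after the adjustment for gene span 5 of the 6. At an adjusted p under 0.01 limma called 0 genes higher and 0 lower, against 937 higher and 1000 lower at an unadjusted p under 0.05. Leaving out any 1 array gave 0 to 0 genes higher, in total or at least 2-fold, with 1 array fewer in the fit. Signal over background limits the dim genes, since about 26.4% of values on each array lay below 0 after background subtraction.

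The replicate numbers did not pair the arrays, as the deviations of arrays with the same number correlated at −0.10, −0.0035 and −0.15 across 12791 genes, and no array correlated best with its own number. Control replicates 1, 2 and 3 correlated best with ODC1 overexpression replicates 3, 1 and 2, at 0.33, 0.23 and 0.30. Deviations sum to 0 within a group, so some positive pairs arise by construction, and whether these arrays shared a batch was not tested. With the replicate number as a block, 2 genes were called higher (PTGS2 and MMP13, both at least 2-fold), 0 lower and 8 lists, and the neuroendocrine list was not called (adjusted p = 0.0625). ODC1 under the block had a log2 difference of 0.39 (adjusted p = 0.659).

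The number of gene lists called was 9, and 5 to 9 when each array was left out. It was 0 by camera with an estimated correlation and 2 by fry, the androgen-regulated list and the list of nuclear receptor cofactors and androgen synthesis genes. The androgen-regulated list had a median of 0.097 to 0.17 with each array left out, called each time (adjusted p from 0.0101 to 0.0332). Its median of 0.15 was not called with an estimated correlation (adjusted p = 0.572), nor was its median of 0.082 after the adjustment for gene span (adjusted p = 0.0848). The estimated correlation of this list was −0.0056, below the preset 0.01, so genes moving together do not account for the first loss. What else gives these losses was not tested. The oxidative phosphorylation, glycolysis and hypoxia and epithelial junction lists were called with each array left out, with medians of −0.48 to −0.28, 0.19 to 0.32 and 0.060 to 0.24. Without control replicate 2, cholesterol biosynthesis (0.19, adjusted p = 0.0272) and the G2/M list (0.24, adjusted p = 0.0272) were called, while without control replicate 3 cholesterol biosynthesis was 0.023 (adjusted p = 0.637). Without ODC1 overexpression replicate 1, keratinocyte differentiation (0.16, adjusted p = 0.0313) and MHC class I antigen presentation (−0.17, adjusted p = 0.04) were called.

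Without ODC1 overexpression replicate 1 the direction reversed for the interferon list, called in the main fit (0.44 to −0.14), and for IFI44L (1.11 to −0.10) and MX1 (0.66 to −0.062), which were not called. The other reversals were of genes and lists that were not called, and their cause was not tested. The polyamine list had a median of −0.0075 without dim probes and −0.034 to 0.0059 with each array left out. With the mean of all probes ATF4 was −0.023, CD68 0.041, DKK3 −0.12, the NRF2 list −0.046 and the stromal, endothelial and leukocyte list 0.036. KRT18 was −0.0020 with an offset of 50 and −0.0022 with normexp and that offset, and the stromal list 0.0038 and 0.0035. Without dim probes the luminal list was 0.011 and the stromal list 0.11. With array quality weights DKK3 was −0.022, KRT18 −0.028, the NF-kB list −0.027 and the NRF2 list −0.013. After the adjustment for gene span CD68 was 0.086, DKK3 −0.058, OAZ1 0.059, SMS −0.022, ZMAT3 −0.0029, the NRF2 list −0.013, the stromal list 0.012 and the unfolded protein response list 0.0040.

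Of 100 genes followed here that were not called, 49 moved by over 1.5 times or across 0 when 1 array was left out. SAT1 went from 0.22 to 0.74, AMD1 from 0.24 to 0.52, TGFBI from 0.25 to 0.92 and THBS1 from 0.27 to 0.70. With each array left out in turn, the log2 difference also crossed 0 for other genes. It went from −0.20 to 0.15 for CD68, −0.15 to 0.31 for CDC20, −0.064 to 0.087 for DKK3, −0.14 to 0.21 for ENO2, −0.025 to 0.26 for ERAP2 and −0.10 to 1.84 for IFI44L. It went from −0.13 to 0.11 for KRT18, −0.22 to 0.010 for KRT7, −0.16 to 0.14 for KRT8, −0.062 to 1.03 for MX1, −0.056 to 0.022 for OAZ1, −0.21 to 0.084 for PHGDH, −0.065 to 0.20 for SMS and −0.13 to 0.23 for ZMAT3. List medians went from −0.035 to 0.24 for G2/M, −0.0073 to 0.16 for keratinocyte differentiation, −0.0084 to 0.12 for mesenchymal and EMT genes, −0.064 to 0.041 for the methionine cycle, −0.19 to 0.075 for MHC class I and −0.062 to 0.10 for MYC targets. They went from −0.083 to 0.11 for NF-kB, −0.024 to 0.16 for NRF2, −0.047 to 0.017 for luminal markers, −0.073 to 0.10 for stromal markers, −0.14 to 0.72 for interferon genes and −0.076 to 0.028 for the unfolded protein response.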

Other observations

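With an intensity trend in the variance model, an alternative fixed before the data were examined, limma called 44 genes, 33 higher and 11 lower, and those named here were chosen after their values were seen. IGFBP3, a binding protein of insulin-like growth factors, had a log2 difference of 1.35 (SE 0.26, adjusted p = 0.0392 with the trend) and rose from an intensity of 711 ± 141 to 1879 ± 594. The matrix genes FBN2, COL8A1 and CTHRC1 rose by 1.43 (SE 0.27), 1.33 (SE 0.25) and 1.1 (SE 0.16). GREM1, a secreted antagonist of bone morphogenetic proteins, rose from 3.97 ± 1.35, around the array median, to 26.5 ± 10.5. The connexin genes GJA1 and GJB2 rose by 1.31 (SE 0.26) and 1.23 (SE 0.20). The chemokine scavenger receptor ACKR3 rose by 1.21 (SE 0.18), the receptor tyrosine kinase KIT by 1.02 (SE 0.16), and CYP24A1, the vitamin D hydroxylase, by 0.98 (SE 0.19). Among the lower genes, GNG11 fell by 1.39 (SE 0.21), G0S2, an inhibitor of adipose triglyceride lipase, by 1.20 (SE 0.20) and PDCD5 by 0.94 (SE 0.19). Without the trend the adjusted p values of these further genes were 0.0731 to 0.194, so none of them was called.

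The tests in the paragraphs that follow were chosen after the results were seen. Oxidative phosphorylation genes were lower as a list (median −0.34), which was called with the preset correlation and not with an estimated one (adjusted p = 0.572). A trend with gene span over all genes is argued against as the whole cause, since the list lay at percentile 0 of 10000 random lists matched on gene span and mean level, and its median was −0.32 after the adjustment for gene span (adjusted p = 1.55e-07 with the preset correlation). The random lists hold genes that need not move together, whereas the estimated correlation between this list's genes was 0.25. The percentile and the p value therefore do not tell how far noise shared by the list's genes gives the shift. A part of the list's lower level may still go with span, as the 21 members with a shorter span had a median of −0.44 (17 lower) and the 21 with a longer span −0.24 (15 lower). The values go with a shift shared with ribosomal protein genes, which are also short and abundant transcripts, as their median was −0.314 with 65 of 77 lower. The median deviation of the ribosomal genes was 0.19, 0.02 and 0.24 in control replicates 1, 2 and 3 and −0.28, −0.18 and 0.04 in ODC1 overexpression replicates 1, 2 and 3. A technical effect on short abundant transcripts, through RNA handling or labelling, and a lower mitochondrial and ribosomal programme in ODC1 overexpression may both give this, and transcript length itself was not tested.

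Interferon response genes were higher as a list (median 0.44), which was called with the preset correlation and not with an estimated one (adjusted p = 0.928). Whether ODC1 overexpression replicate 1 alone gives this or all 3 ODC1 overexpression arrays share a difference stays open. Of these arrays 1, replicate 1, had a list median above every control array, and the median without it was −0.144 (adjusted p = 0.278), with 27 of 42 members lower. Control replicate 1 had the second highest level, at a median deviation of 0.37, and without replicate 1 of either group the median was 0.12, with 27 of 42 higher. SAMD9, RSAD2, IFIT2 and HERC5, named after their values were seen, lay above all control arrays in all 3 ODC1 overexpression arrays. These were 4 of 42 members, where 1699 of all 20046 genes were separated upwards in the same way. Their log2 differences were 0.90, 0.64, 0.45 and 0.34 without ODC1 overexpression replicate 1. As they were picked for this separation, the differences without ODC1 overexpression replicate 1 had to be positive and cannot decide the question. A candidate explanation for the high level of that array is an interferon response in its culture, for example to transfected DNA, and whether a repeat culture would show it is untested.

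ODC1 signal overlapped between the groups although the design names it as overexpressed. Saturation of the probe is argued against, as its highest value was 12.3% of the highest intensity on the array. An exchange of control replicate 3 with ODC1 overexpression replicate 3 would end the overlap. Exchanging them gave 18 genes with a moderated t beyond 5, fewer than the 40 of the labels. A true exchange was predicted to give more such genes than the labels, so this value goes against it. The exchange is not excluded, since it gave more such genes than any of the other splits (highest 6). On other measures it did not stand out from these, with 1396 genes at an unadjusted p under 0.05 (1937 for the labels, highest of the other splits 1670), a highest absolute t of 7.42 (9.28 for the labels, 8.57 in another split), 5 called lists (9 for the labels, up to 9 in another split) and 0 genes past the threshold (6 for the labels). Whether the probe lies outside the transfected sequence, so that the plasmid's transcript may be missed, cannot be told apart from weak overexpression with 1 ODC1 probe and no probe sequence used here. A biological loss of the ODC1 transcript in some cultures stays open as untested.

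The 10 splits of the 6 arrays into 3 and 3 cannot give a share under 0.05. As many genes past the threshold came from 1 of the 10 splits (6 for the labels, highest of the others 0), as many at least 2-fold from 1 of the 10 (6 for the labels, highest of the others 0), and as many called lists from 2 of the 10 (9 for the labels, highest of the others 9). The first principal component held 41.85% of the variance, with control replicates 1, 2 and 3 at −25.9, −1.33 and −19.7 and ODC1 overexpression replicates 1, 2 and 3 at 25.2, 18.6 and 3.08. Across the brighter genes, control replicate 2 correlated at 0.9861, 0.9877 and 0.99 with ODC1 overexpression replicates 1, 2 and 3. Its correlations with control replicates 1 and 3 were lower, at 0.9844 and 0.9832. The ODC1 overexpression arrays correlated with each other at 0.9863 to 0.9914.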
